A study of Mus musculus with 2 samples.

How the data were processed

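Translating ribosome affinity purification (TRAP) followed by RNA sequencing was applied to the ventral striatum of adult mice carrying a ribosomal protein, Rpl10a, fused to the green fluorescent protein EGFP under regulatory sequence of Stard5. Per the labels' protocols, the tissue was dissected and homogenised, polysomes carrying the tag were pulled down with monoclonal antibodies against EGFP on magnetic beads, and RNA was purified from the pulled-down material. The mice were controls without treatment. The series holds 2 libraries of the pulled-down fraction, replicate 1 and replicate 2, which form 1 group. No library of the input RNA, of another mouse line or of another tissue was analysed here, so no enrichment over the tissue and no difference between conditions could be computed. The labels do not say whether the replicates came from separate animals or pools, so the spread between them may be technical.

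The deposited files hold raw counts of reads per gene symbol. Per the submitters' processing notes, the tools were STAR 2.0.0e, an aligner, and HTSeq, a read counter, with the mouse build mm10. The annotation, the strand setting and any filter on reads are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads that fit near-identical copies, such as haemoglobin genes, may be split or lost. Each file closed with summary lines, and 6 lines that name no gene were left out of all totals and tests. Of these, reads outside annotated exons made up 22.8% of all counted reads in replicate 1 and 31.0% in replicate 2. Reads with more than a single alignment made up 27.9% and 13.6%, and ambiguous reads 1.84% and 2.08%. Lines for unaligned reads and for low alignment quality held 0 reads in both libraries. The remaining 32531 symbols held 25830282 reads in replicate 1 and 29574781 in replicate 2.

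Counts were converted to CPM, reads per 1000000 reads assigned to genes. A gene counted as detected at 1 CPM or more in both libraries, which is 25.8 reads in replicate 1 and 29.6 in replicate 2. Levels are given as mean ± SD over the 2 libraries, and single libraries with exact Poisson 95% intervals. Shares of reads carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A floor was set at 3 reads, or 0.116 CPM in replicate 1 and 0.101 CPM in replicate 2. The exact 95% interval of a count of 0 reaches higher, to 0.143 and 0.125 CPM. CPM of different genes also depends on transcript length, so values per kilobase of exon were computed as an alternative. Exon length, GC content and coordinates came from the GENCODE M21 annotation of GRCm38, matched by symbol: 23113 symbols matched a single gene, and 11465 of the 12374 detected genes (92.7%) had a length.

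Gene lists were fixed before the data were examined: markers of striatal neuron types, compartments and regions, markers of other neurons, glia, vessels and blood, receptor and signalling families, and genes that report nuclear RNA, dissection and sex. Of 385 distinct members, 369 were found among the symbols. The 13 mitochondrial messenger RNAs were not found under the fixed names, and their list is not analysed here. Genes named in the text were chosen by a rule also fixed beforehand: of each list the up to 4 members with the highest mean CPM and the member with the lowest, then Drd1, Drd2, Stard5 and Rpl10a. Of all other genes, the rule took the 15 with the highest mean CPM and, in each direction, the 6 with the largest log2 ratio between the libraries among those at a mean of 5 CPM or more and past the test. Names outside this rule are marked as chosen after their values were seen, and a few genes that the rule takes are not reported here.

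List medians of mean log2(CPM + 1) were compared across genes by 2-sided permutation tests, exact where all splits could be listed and with 100000 resamples otherwise, with Benjamini-Hochberg adjustment. These tests compare levels of different genes within 1 group, and genes are not independent replicates. The level of each list is also given as the percentile of its median among 10000 random lists of detected genes. Between the libraries, the reads of each detected gene were compared by a 2-sided exact binomial test with library sizes scaled by the trimmed mean of M-values (TMM) of edgeR 4.0.16, with a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold ratio required. That test compares 2 libraries of the same group, not conditions, and takes in counting error only, with no spread between libraries. The median log2 ratio of each list is given as a percentile among 10000 random lists matched on expression in 20 bins. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design and 1 residual degree of freedom. Trends of the log2 ratio on exon length or GC content were removed by lowess smoothing, and medians of lists carry bootstrap 95% intervals from 10000 draws. Those draws resample the genes of a list, which are not independent replicates, so the intervals hold no spread between libraries.

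In libraries simulated at the same depths with Poisson counting error only and 200 of 12374 genes changed 3-fold, the binomial test recovered 100% of them with 1 false call. That simulation held no spread between libraries, so it does not measure false calls from such spread. The permutation test, run on simulated lists of 6 genes without a difference, gave p below 0.05 in 6.1% of 1000 draws. Alternatives covered size factors of DESeq2 1.42.0 and total counts, other expression filters and fold limits, edgeR's exact test, another pseudocount, means in place of medians, values per kilobase, another background, and each library alone. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3.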

Results

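The series profiled RNA bound to tagged ribosomes in the ventral striatum of Stard5-TRAP mice of line JX5852, in which cells that use the Stard5 regulatory sequence carry EGFP on ribosomal protein L10a. Its stated purpose was to profile neurons of this region. The 2 libraries of the pulled-down RNA, replicates 1 and 2 of the only group, held 25830282 and 29574781 reads in genes. In replicate 1, 16441 genes had at least 1 read, and in replicate 2, 18230. At 1 CPM or more, 12374 genes were detected in both libraries, of which 7823 reached 10 CPM, 1915 reached 100 CPM and 67 reached 1000 CPM in both. The 45S ribosomal RNA precursor Rn45s took 6.89% of the reads in genes in replicate 1 and 6.21% in replicate 2.

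Stard5, a lipid transfer protein of the START domain family whose regulatory sequence drives the tag, was detected at 111 ± 78.8 CPM (SD, n = 2), rank 1986 of all genes by mean CPM. The gene (ENSMUSG00000046027.17) lies on chromosome 7 from 83631959 to 83653127 on the plus strand of GRCm38. Its level was 166 CPM (95% interval 161 to 171) in replicate 1 and 54.9 CPM (52.2 to 57.6) in replicate 2, a log2 ratio of -1.57 that passed the binomial test on reads. Rpl10a, the gene of the tagged protein (chromosome 17, 28328471 to 28331033), stood at 99.5 and 57.5 CPM in replicates 1 and 2, with a mean of 78.5 ± 29.7 CPM (n = 2). Rpl10a ranked 21 of 85 cytoplasmic ribosomal protein genes, and reads of the transgene cannot be separated from those of the native gene. The median of those 85 genes, a group chosen after the data had been seen, was also lower in replicate 2, at 30.8 CPM against 55.5 CPM in replicate 1. Among START domain genes, 11 of 15 were detected: the ceramide transporter gene Col4a3bp was at 159 ± 6.92 CPM, below Stard5 in replicate 1 and above it in replicate 2, Stard7 at 87.4 ± 19 CPM, Dlc1 at 39.5 ± 23.8 CPM and Stard6, the lowest, at 0.331 ± 0.249 CPM. Of the exon bases of Stard5, 23.9% overlap the neighbouring genes Il16 and Gm45838. Il16, chosen after its value was seen, was at 5.77 ± 1.32 CPM.

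Markers of striatal spiny projection neurons, the GABAergic output neurons of the striatum, stood above those of 12 other cell types. All 19 general spiny neuron markers were detected above 10 CPM in both libraries and 17 above 100 CPM, with a list median of 418 CPM at percentile 100 of random lists. The highest were the cAMP-regulated phosphoprotein gene Arpp21 at 2550.1 ± 688 CPM, the G protein subunit gene Gnal, which couples dopamine and adenosine receptors to adenylyl cyclase, at 2482 ± 281 CPM, the striatal phosphodiesterase gene Pde10a at 1925 ± 67.6 CPM and the transcription factor gene Meis2 at 751 ± 185 CPM (SD, n = 2). The lowest, the actin crosslinker gene Actn2, was at 36.5 ± 2.69 CPM. The list median lay above that of each of 12 other cell type lists, with adjusted p from 8e-05 to 0.00129 in exact or permutation tests across genes. These p-values compare different genes and do not measure enrichment over the tissue.

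Oligodendrocyte markers came closest to the spiny neuron list, 2.98 ± 0.73 log2 units below it (n = 2). Their median was 65.4 CPM, and the myelin genes Mbp, Cnp and Mobp stood at 327 ± 65.6, 181 ± 92.2 and 161 ± 28.9 CPM, with Opalin lowest at 4.41 ± 2.85 CPM. Astrocyte markers had a median of 17.2 CPM, 4.72 ± 1.04 log2 units below the spiny neurons, and were led by the glutamate transporter genes Slc1a2 at 1619 ± 1241 CPM and Slc1a3 at 113 ± 101 CPM, the aldolase gene Aldoc at 153 ± 102 CPM and the water channel gene Aqp4 at 28.8 ± 25.6 CPM, with Aldh1l1 lowest at 5.12 ± 4.23 CPM. Markers of oligodendrocyte precursors had a median of 14.3 CPM (Vcan 52.2 ± 23.6, Pdgfra 36.6 ± 31.3, C1ql1 1.18 ± 0.628 CPM) and those of microglia 12.5 CPM (Ctss 47.4 ± 5.50, Csf1r 38.8 ± 15.3, Mrc1 0.662 ± 0.881 CPM). Endothelial and mural cell markers were low, at a median of 4.71 CPM, with 9 of 12 detected and the pericyte gene Rgs5 highest at 10.1 ± 4.55 CPM. Of 8 ependymal and choroid plexus markers 2 were detected, Enpp2 at 141 ± 56.4 CPM and Kl at 16.6 ± 5.51 CPM. The list median was 0.211 CPM, with Foxj1 at 0.776 CPM and Folr1 at 0 reads, so Enpp2 and Kl alone do not show RNA of these cells. Red blood cell genes were low, with Alas2 at 3.68 ± 2.35 CPM.

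Markers of other neurons were low. Cholinergic interneuron markers had a median of 13.3 CPM with 6 of 8 detected: the choline transporter gene Slc5a7 stood at 57.5 ± 9.87 CPM, the transcription factor gene Lhx8 at 26.2 ± 3.42 CPM and choline acetyltransferase, Chat, at 17.2 ± 6.53 CPM (SD, n = 2). Of 12 GABAergic interneuron markers 5 were detected, with the somatostatin gene Sst at 53.6 ± 22.3 CPM, Lhx6 at 48.3 ± 10 CPM and the nitric oxide synthase gene Nos1 at 23.9 ± 5.88 CPM. The vesicular glutamate transporter genes Slc17a6 and Slc17a7 were at 13.7 ± 9.21 and 4.27 ± 1.66 CPM, and the catecholamine genes Slc18a2, Ddc and Th at 13.5 ± 0.551, 12.2 ± 5.14 and 7.52 ± 2.47 CPM. Vip, Gbx2, Emx1 and En1 had 0 reads in both libraries, which by counting error alone allows up to 0.143 CPM in replicate 1 and 0.125 CPM in replicate 2. The ribosomal protein genes Rpl26 and Rpl36al, chosen after their values were seen, also had 0 reads, so a 0 may reflect reads not assigned to a symbol. Of the exon bases of Gbx2, 43.5% overlap D130058E05Rik. The medians of the GABAergic, glutamatergic and dopaminergic lists were 1.81, 1.67 and 2.06 CPM, with 5 of 12, 4 of 9 and 4 of 8 members detected.

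**Figure D1:**
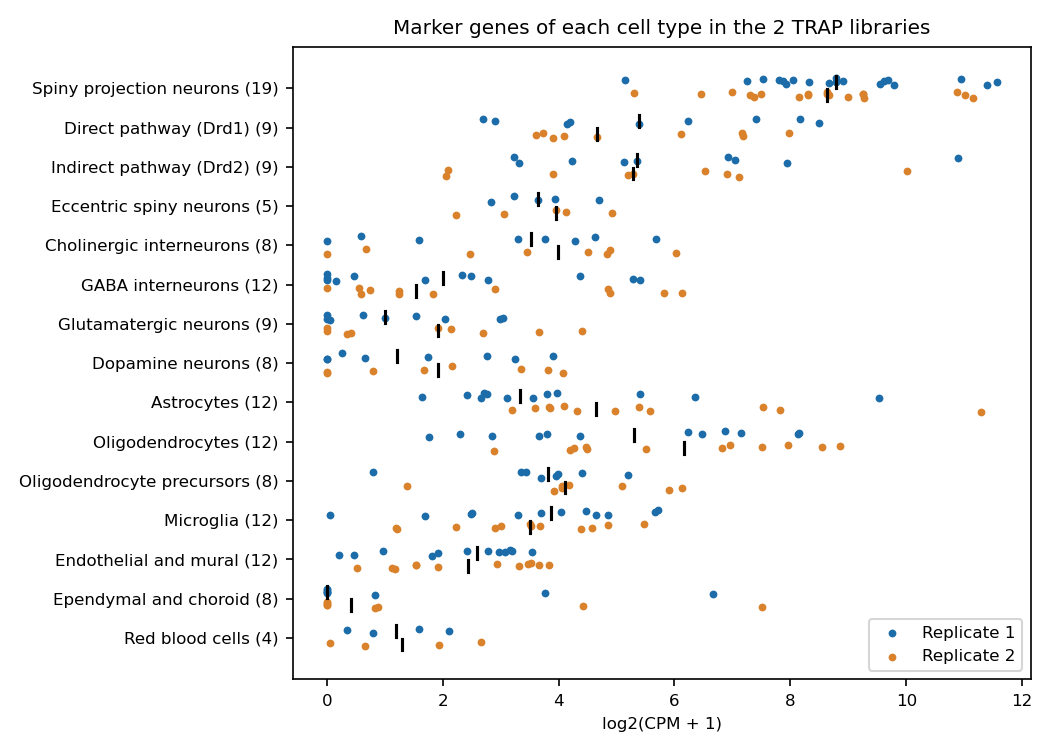
Levels of marker genes by cell type, as log2(CPM + 1) on the horizontal axis, with each point a gene in replicate 1 (blue) or replicate 2 (orange), black ticks at the list medians and the number of genes in brackets. The median of the spiny projection neuron markers, 418 CPM, lies to the right of the medians of the 12 other cell type lists outside the direct and indirect pathways.

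Markers of direct and indirect pathway spiny neurons, which carry the dopamine receptors Drd1 and Drd2, were both detected, and the marker lists did not differ detectably. Without an input library, these levels do not show which of these neurons carry the tag. All 9 direct pathway markers and all 9 indirect pathway markers were detected. Drd1 (ENSMUSG00000021478.6, chromosome 13, 54051183 to 54055705, minus strand) was at 268 ± 25.5 CPM and Drd2 (ENSMUSG00000032259.8, chromosome 9, 49340627 to 49408177, plus strand) at 192 ± 76.1 CPM (SD, n = 2). On the direct pathway side, the tachykinin gene Tac1 stood at 252 ± 151 CPM, the prodynorphin gene Pdyn at 155 ± 17.5 CPM, Sfxn1 at 71.2 ± 4.61 CPM and Eya1, the lowest, at 8.87 ± 4.77 CPM. On the indirect side, the enkephalin gene Penk stood at 1468 ± 617 CPM, the kainate receptor gene Grik3 at 125 ± 8.50 CPM, the adenosine receptor gene Adora2a at 106 ± 20.5 CPM and Plxdc1, the lowest, at 5.82 ± 3.65 CPM. The difference of list medians, direct minus indirect, was -0.67 on the log2 scale (exact permutation test across genes, p = 0.798). It was 0.03 in replicate 1 and -0.61 in replicate 2, so its sign differed between the libraries.

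Of the reads of Drd1 and Drd2 together, Drd1 had 53.8% (Clopper-Pearson 95% interval 53.0 to 54.7) in replicate 1 and 64.5% (63.6 to 65.4) in replicate 2, a mean of 59.2% ± 7.52 (SD, n = 2). The intervals of the libraries did not overlap, with Drd1 at 7399 and 7403 reads and Drd2 at 6342 and 4079 reads. Per kilobase of exon the Drd1 share was 50.5%, since the annotated exons of Drd1 span 3628 bases and those of Drd2 2547. Eccentric spiny neuron markers were low, with a median of 11.5 CPM, Otof at 27.0 ± 3.06 CPM and Col11a1 at 4.92 ± 1.75 CPM.

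Markers of both neurochemical compartments of the striatum, and of its ventral and dorsolateral parts, were present. In the patch list, the exchange factor gene Rasgrp1 stood at 1636 ± 398 CPM, the imprinted gene Nnat at 156 ± 63.6 CPM, Tshz1 at 116 ± 36.2 CPM and Kremen1 at 6.27 ± 2.95 CPM. In the matrix list, the synaptic vesicle gene Sv2b stood at 398 ± 19 CPM, the ephrin receptor gene Epha4 at 204 ± 29.5 CPM, the calbindin gene Calb1 at 67.9 ± 10.5 CPM and Id4 at 26.1 ± 10.8 CPM (SD, n = 2). All 13 ventral markers were detected, with Peg10 at 1114 ± 351 CPM, Wfs1 at 541 ± 84.7 CPM, Dlk1 at 204 ± 9.61 CPM, Zcchc12 at 137 ± 13.2 CPM and Calb2, the lowest, at 1.60 ± 0.459 CPM. Of the dorsolateral markers, Reln was at 83.9 ± 52.3 CPM, Gpr155 at 81.0 ± 2.19 CPM, the cannabinoid receptor gene Cnr1 at 46.8 ± 16.8 CPM and Coch at 2.90 ± 0.591 CPM. Patch minus matrix was -0.45 log2 units (exact permutation test, p = 1) and ventral minus dorsolateral 0.08 (exact permutation test, p = 0.982). Neither sign held in both libraries, with 0.11 and -0.76 for patch minus matrix and 1.21 and -0.15 for ventral minus dorsolateral in replicates 1 and 2. Per kilobase of exon, ventral minus dorsolateral was 2.42 (exact permutation test, p = 0.126).

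Most receptor families were led by the same gene in both libraries. Drd1 and Drd2 led the dopamine receptors, above Drd3 at 16.4 ± 3.40 CPM and Drd5 at 1.58 ± 0.611 CPM, with 48.6% of the exon bases of Drd5 shared with Gm26560. Htr2c led the serotonin receptors at 155 ± 0.980 CPM, 2.77 ± 0.10 log2 units above Htr2a. The muscarinic receptor gene Chrm1 stood at 63.9 ± 3.67 CPM, 1.93 ± 0.16 log2 units above Chrm4, and Adra1a led the adrenergic receptors at 25.9 ± 1.25 CPM. The opioid receptor genes Oprk1, Oprm1 and Oprd1 were at 50.6 ± 9.97, 41.6 ± 3.32 and 28.2 ± 8.74 CPM, and the order of the first pair changed between the libraries. The adenosine receptor genes Adora1 and Adora2a stood at 121 ± 32.4 and 106 ± 20.5 CPM, with 20.1% of the exon bases of Adora1 shared with Mybph. In the endocannabinoid list, the lipase gene Mgll was at 52.2 ± 8.77 CPM, and its order with Cnr1 changed between the libraries.

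For glutamate and GABA, the AMPA receptor list lay at percentile 99.97 of random lists, led by Gria2 at 1090.1 ± 177 CPM, ahead of Gria3 at 411 ± 24.1 CPM by 1.40 ± 0.15 log2 units (SD, n = 2). Grin2b led the NMDA receptors at 279.6 ± 66.8 CPM and Grm5 the metabotropic receptors at 355 ± 71.6 CPM. The kainate receptor genes Grik2 and Grik3 were at 127 ± 28.5 and 125 ± 8.50 CPM, and their order changed between the libraries. The GABA synthesis and transport list also lay at percentile 99.97, with the glutamate decarboxylase genes Gad2 at 2959.6 ± 329 CPM and Gad1 at 505 ± 91.0 CPM. In the cAMP pathway, 16 of 17 phosphodiesterase genes were detected, led by Pde10a with Pde4b at 669 ± 174 CPM, and Adcy5 led the adenylyl cyclases at 316 ± 2.75 CPM, 1.42 ± 0.09 log2 units above Adcy9. Among regulators of G protein signalling, Rgs8 was at 410.2 ± 104 CPM, Rgs2 at 339 ± 160.3 CPM and Rgs17 at 338 ± 3.40 CPM. Of 19 neuropeptide genes 10 were detected, with Scg2 at 596 ± 52.0 CPM next after Penk. Per kilobase of exon, 8 of the 18 families kept their leading gene, and Drd2, Chrm4, Adra2c, Oprd1, Adora2a, Grin1, Grik3, Grm3, Rgs2 and Stard5 led the others.

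**Figure D2:**
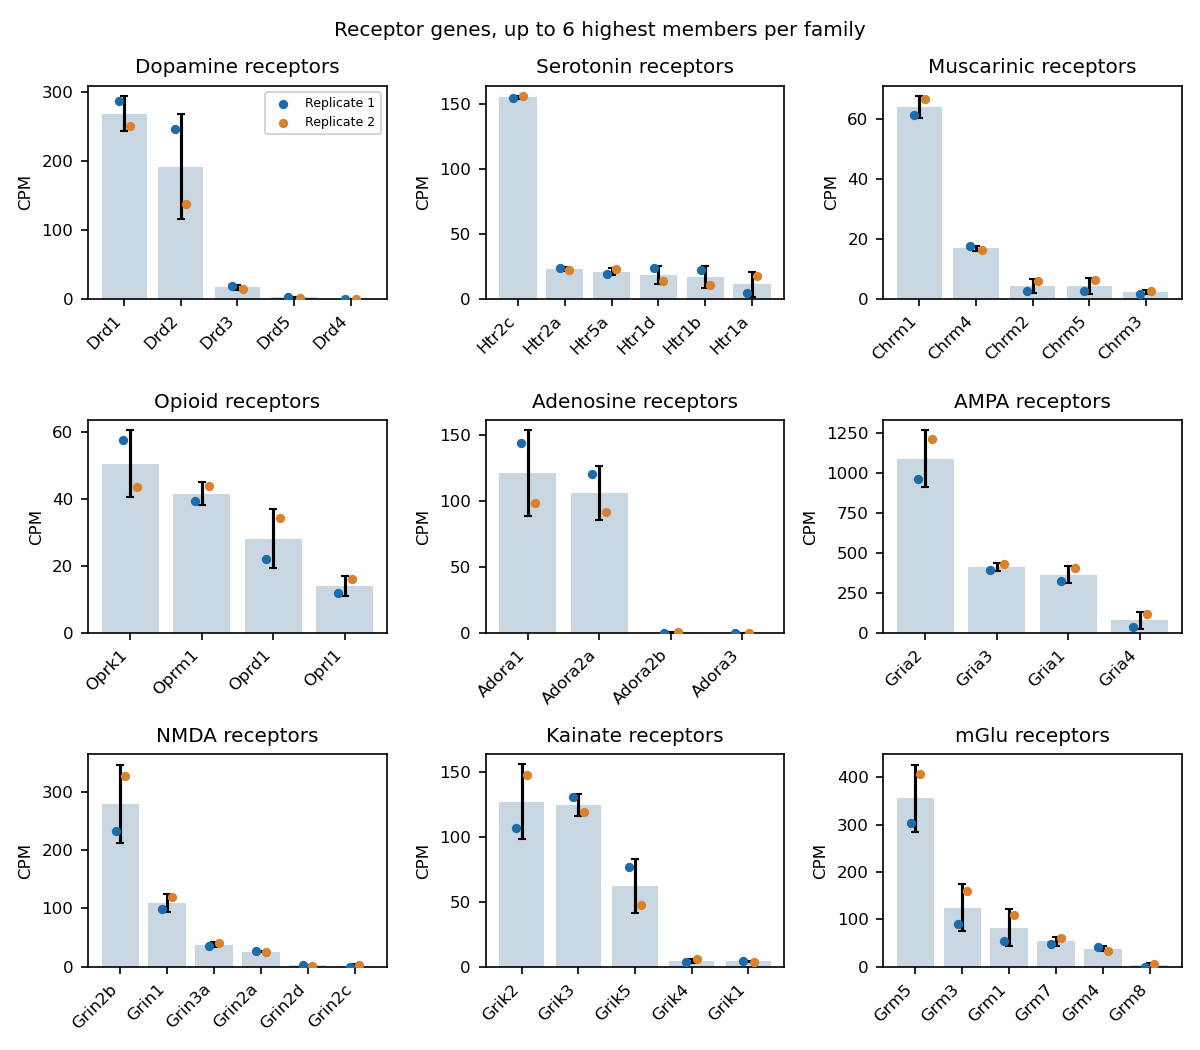
CPM of the up to 6 highest genes of 9 receptor families on linear axes from 0, with bars for the mean of the 2 libraries, error bars for the SD, and points for replicate 1 (blue) and replicate 2 (orange). Drd1, Htr2c, Chrm1, Gria2, Grin2b and Grm5 lead their families in both libraries, with Gria2 highest at 1090.1 ± 177 CPM.

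The most abundant transcripts outside the lists, taken without a filter on nuclear or mitochondrial origin, included Rn45s at 65478 ± 4769 CPM. The synaptic fusion gene Snap25 stood at 7279 ± 2642 CPM, the microtubule gene Map1b at 6740 ± 2097 CPM, Ndrg4 at 5472 ± 594 CPM, and the adaptor protein gene Ywhaz at 4771 ± 1003 CPM (SD, n = 2). The mitochondrial leucyl-tRNA synthetase gene Lars2 was at 4024 ± 692 CPM, the calmodulin gene Calm2 at 2171 ± 1063 CPM, and the unnamed transcript AK140265 at 2912 ± 1606 CPM. Prkcb, Fkbp1a, Ywhae, Hsp90ab1, Arf3 and Ppp3ca lay between 2078 and 2648 CPM.

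Most astrocyte markers were higher in replicate 2, as were some oligodendrocyte markers and noncoding nuclear RNAs, while some immediate early genes were higher in replicate 1. Of 12 astrocyte markers, 10 passed the binomial test on reads as higher in replicate 2 and 0 as higher in replicate 1, with a median log2 ratio of 1.73, among them Slc1a3 (2.18), Aqp4 (2.15) and Slc1a2 (1.78), while Aldoc stood at 80.8 CPM in replicate 1 and 225 CPM in replicate 2. Of 12 oligodendrocyte markers, 5 passed as higher in replicate 2 and 0 as higher in replicate 1, with a median of 0.75 and Cnp at 1.11. Of 7 tested oligodendrocyte precursor markers only Pdgfra, at 2.04, passed. Of 9 nuclear and long noncoding RNAs, 6 passed as higher in replicate 2 and 0 as higher in replicate 1, including Malat1 at 1.51, Meg3 at 1.38 and Snhg11 at 1.64, while Peg13 and Xist stood at -0.16 and -0.80, and the interval of the list median was -0.16 to 1.64. Of 15 tested immediate early genes, 5 passed as higher in replicate 1 and 0 as higher in replicate 2, with a median of -0.70 (-0.45 with the trend on exon length removed), Egr1 at -1.30 and Fosl2 at -1.02. Counts were the same in each of these lists when adjusted over the list alone.

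Neuronal lists went both ways. The general spiny neuron markers had a median log2 ratio of -0.33, and 0 of 19 passed with a 2-fold ratio. The direct pathway list had a median of -0.11 (bootstrap 95% interval -1.28 to 0.82). Of its 9 members, 2 passed as higher in replicate 1, with Tac1 at -1.28, and 1 as higher in replicate 2, Eya1 at 1.18. The indirect pathway list had a median of -0.37 (-1.34 to -0.05), and 2 of 9 passed as higher in replicate 1, with Plxdc1 at -1.34, and 0 as higher in replicate 2. The patch list had a median of -0.62 (bootstrap 95% interval -0.83 to 0.19), though its only member past the test, Kremen1 at 1.02, was higher in replicate 2. The cholinergic, GABAergic interneuron and glutamatergic lists had medians of 0.49, 0.53 and 0.85, with 1 member of each past the test as higher in replicate 2. Medians of the microglia and endothelial lists were -0.42 and -0.23 (-0.14 and -0.34 with the trend on exon length removed, and 0.57 for the endothelial list with a filter at a mean of 5 CPM), with 1 of 11 and 2 of 9 members past the test as higher in replicate 1 and 0 as higher in replicate 2, while 2 of 11 and 4 of 9 had a ratio above 0. Heat shock and dissection stress genes had a median of -0.63, with Dnajb1 at -1.42 past the test and Hsph1, the most abundant at 1391 ± 69.3 CPM, at -0.08. Against random lists matched on expression, the astrocyte, oligodendrocyte, precursor, GABA synthesis, nuclear RNA and Y-linked lists lay in the highest 2.5% towards replicate 2. The driver (Stard5 and Rpl10a), spiny neuron, patch, dopamine receptor, immediate early and stress lists lay in the highest 2.5% towards replicate 1. With the trend on exon length removed, the dopamine receptor list left that range, at percentile 13.2, and the ventral, dorsolateral and GABAergic interneuron lists came within the highest 2.5% towards replicate 2, at percentiles 99.92, 97.55 and 99.93. With a filter at a mean of 5 CPM, the dopamine receptor and stress lists left, at percentiles 11.8 and 5.69, and the dorsolateral list came in, at 98.9. All 4 Y-linked genes were detected in both libraries, led by Ddx3y at 70.1 ± 20.3 CPM, while Xist, transcribed from the inactive X chromosome of females, was at 2.02 ± 0.806 CPM (SD, n = 2).

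Over all 12374 detected genes, 2137 (17.3%) passed the binomial test with a 2-fold ratio, 958 higher in replicate 1 and 1179 in replicate 2. The largest ratios towards replicate 2 were those of Cfap44 at 3.70, Pcdhb5 at 3.64, AK039862 at 3.63, AK143030 at 3.42, Itih3 at 3.36 and AK035422 at 3.35. Towards replicate 1 they were those of Musk at -3.62, Rcsd1 at -3.53, AK163129 at -3.23, AK018074 at -3.18, Smyd1 at -2.91 and Bola1 at -2.88. The median absolute log2 ratio was 0.44, log2(CPM + 1) correlated across genes with Pearson's r of 0.946 and Spearman's rho of 0.942, and the biological coefficient of variation was 0.355. Genes are not independent replicates in these correlations. The chi-square of the counts was 129 per degree of freedom, so the files hold separate libraries. With the edgeR exact test and the common dispersion of the same libraries, 0 genes passed at an adjusted p of 0.05 and 754 had an unadjusted p below 0.05. That dispersion takes in the difference between the libraries, so few genes can pass.

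**Figure D3:**
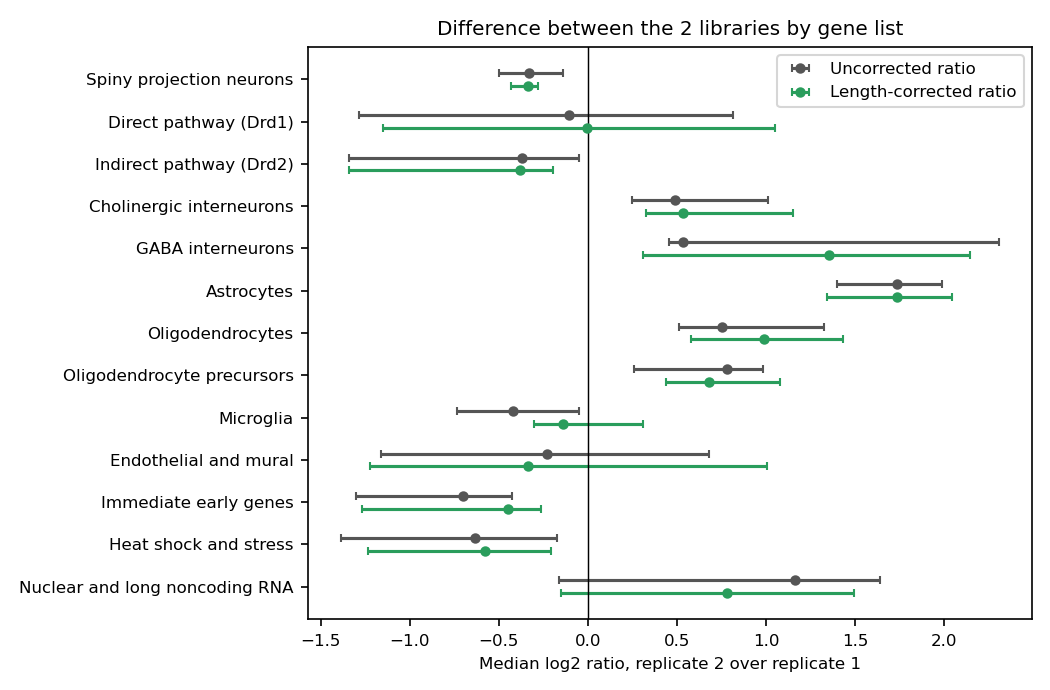
Median log2 ratio of replicate 2 over replicate 1 for 13 gene lists, before (grey) and after (green) removal of the trend on exon length, with bootstrap 95% intervals over the genes of each list. The astrocyte list lies farthest towards replicate 2 at 1.73, and immediate early genes lie towards replicate 1 at -0.70 before the removal and -0.45 after it.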

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

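Alternatives on exon length and GC trends between the libraries were chosen after the data had been seen, and all others before the data were examined. Spiny neuron markers lay above the other 12 cell type lists under each alternative run for that comparison. Among alternatives for main results 46 were counted as kept, 13 moved and 3 reversed. A list comparison counted as kept if its sign and its side of the adjusted p limit of 0.05 were unchanged, whatever its size. Ventral minus dorsolateral thus counted as kept at 2.42 per kilobase against 0.08 in the main run. Among alternatives for single genes and lists 911 stayed within the limits set for them and 130 moved, but list ratios inside the middle 95% of random lists counted as kept even where their sign changed. For single genes and the Drd1 share the limit was 1 SD. With 2 libraries, each library alone always lies within 1 SD of the mean, so those alternatives were kept in advance and show no robustness. Single libraries gave -0.61 to 0.028 for direct minus indirect pathway markers, -0.76 to 0.11 for patch minus matrix and -0.15 to 1.21 for ventral minus dorsolateral. The count of genes that differ between the libraries was 5597 with no filter (2003 higher in replicate 1 and 3594 in replicate 2), 4730 at a 1.5-fold limit, 9745 with no fold limit and 0 with edgeR's exact test and common dispersion (754 at an unadjusted p below 0.05). That dispersion takes in the difference between the libraries, so few genes can pass. With the trend on exon length removed the count from the binomial test was 1701, 637 higher in replicate 1 and 1064 in replicate 2. Pearson's r was 0.961 with no filter and 0.928 at a mean of 5 CPM, and the coefficient of variation 0.689 and 0.345, with more or fewer low genes included. Values per kilobase gave a Drd1 share of 50.5%, 8 leading genes kept of 18 and 8 lists in the top 2.5% of random lists in place of 5. With all genes as background, 23 lists lay in the top 2.5% and 0 in the lowest 2.5%, because undetected genes joined the random lists. The cause of the sign changes between libraries was not tested. No paired analysis was possible because the series has 1 group. Leaving out a library gives no value for differences or agreement between the libraries. Depth limits genes near the floor of 0.116 and 0.101 CPM.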

Other observations

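Gene groups chosen after the data had been seen add detail on excitability and transcription. All 20 potassium channel genes examined were detected, among them Kcna1 at 435 ± 35.2 CPM and Kcna2 at 401 ± 16.9 CPM (SD, n = 2). All 21 sodium and calcium channel genes were detected, led by the R-type calcium channel gene Cacna1e at 816 ± 175 CPM and Cacnb4 at 771 ± 63.2 CPM, with the sodium channel gene Scn8a at 414 ± 59.3 CPM. Among 13 G protein alpha subunit genes, Gnal at 2482 ± 281 CPM stood above Gnao1 at 1551 ± 124 CPM and Gnas at 938 ± 51.4 CPM. Of 26 transcription factor genes of the striatum and its embryonic source, 24 were detected, with Foxp1 at 697 ± 122 CPM, Bcl11b at 424 ± 24.5 CPM and Foxp2 at 243 ± 16.8 CPM.

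Of 20 nuclear hormone receptor genes 16 were detected, with the thyroid hormone receptor genes Thrb and Thra at 191 ± 45 and 158 ± 33.4 CPM and the retinoic acid receptor gene Rarb at 155 ± 39.5 CPM. The progesterone receptor gene Pgr stood at 54.1 ± 9.84 CPM. Of 12 neurotrophin pathway genes 6 were detected, and Ntrk2, the receptor gene for BDNF, stood at 395 ± 159 CPM while Bdnf itself was at 0.97 ± 1.21 CPM, with 3 reads in replicate 1 and 54 in replicate 2. Ntrk2 was at 283 CPM in replicate 1 and 507 CPM in replicate 2, and the cells that it came from cannot be told here. Of 20 imprinted genes 18 were detected and 12 reached 100 CPM in both libraries, with Peg3 at 1098 ± 248 CPM. The median of 85 ribosomal protein genes was 55.5 CPM in replicate 1 and 30.8 CPM in replicate 2.

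For the patterns below, the tests of exon length on all genes, of glial and vascular lists, of nuclear RNA and of both explanations for the astrocyte and oligodendrocyte markers were chosen after the result was seen. The GC content test and both tests for Stard5 were also added once the data were open, but written down before their own results were seen. The comparison of astrocyte with microglia markers was added once the intervals of both lists were known. No biological explanation was tested, since the series has 1 group.

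The first pattern is the set of 2137 genes that differ between the libraries. Ratios of replicate 2 over replicate 1 increased with exon length (Spearman's rho across genes 0.29), yet 89.3% of the number of calls among genes with a known length was left after that trend was removed, 1701 against 1904, and 98% after removal of the trend on GC content, which argues against either as the whole cause. Medians of 3 of the 5 glial and vascular lists lay towards replicate 2 after removal of the length trend, and the intervals of the microglia and endothelial lists included 0 (microglia -0.73 to -0.05 before removal), so that test left RNA from these cells open. A larger share of nuclear RNA in replicate 2 may contribute, but the corrected median of the noncoding RNA list was 0.78 with an interval from -0.15 to 1.49, which keeps it open. The share of uniquely aligned reads outside annotated exons was 31.6% in replicate 1 and 35.8% in replicate 2.

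The second pattern is the higher level of astrocyte and oligodendrocyte markers in replicate 2, led by Slc1a2 at 741 CPM in replicate 1 and 2496 CPM in replicate 2. A lower share of RNA from tagged cells would raise every other cell type alike only if untagged RNA came evenly from all of them, which was not tested. The corrected astrocyte median lay 1.88 log2 units (95% interval over genes 1.34 to 2.23) above that of microglia. It lay 2.07 (0.67 to 2.79) above that of the endothelial list, which was -0.34 with 4 of 9 ratios above 0. These gaps argue against an even rise as the whole cause and leave an uneven one open. With a filter at a mean of 5 CPM and no length correction, the endothelial median was 0.57 over 6 members, which goes with a lower share. Other lists also went with a lower share, with corrected medians of 0.68 (0.43 to 1.07) for oligodendrocyte precursors, 7 of 7 with a ratio above 0, and 0.53 (0.33 to 1.15) for cholinergic markers, 6 of 6. GABAergic interneuron markers were at 1.35 (0.31 to 2.14), 5 of 5, glutamatergic markers at 0.98 (0.74 to 1.48), 4 of 4, and dopaminergic markers at 0.47 (-0.08 to 0.98), 2 of 4. An even rise may thus add to the pattern without accounting for the gaps to the microglia and endothelial lists. Removing the trend on exon length left 100.2% of the astrocyte median, and all 12 markers of each list were detected. A candidate explanation is more RNA of astrocytes and oligodendrocytes in the pulled-down material of replicate 2. It could come through untagged carryover, which the antibody step is meant to remove, or from tagged cells of these types, and the files cannot tell these apart. Such carryover would itself lower the share of RNA from tagged cells, but unevenly over the other cell types.

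The third pattern is the lower Stard5 level in replicate 2, with a log2 ratio of -1.57. Removing the trend on exon length left 102.4% of it, at -1.61. Dilution of RNA from tagged cells stays open: the median of the spiny neuron markers was -0.33 (95% interval -0.50 to -0.14), short of -0.79, 50% of the ratio of Stard5 and the bound set beforehand, but that bound was wrong for this design, because untagged RNA of the striatum also carries these abundant markers and without an input library the tagged cells cannot be set apart from other spiny neurons. Differences in Stard5 itself, in reads from the transgene or in which cells carry the tag may also contribute, and none of these was tested.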
